A study of Hippocampus with 6 samples.

How the data were processed

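Total RNA was extracted with TRIzol from the hippocampus of 3 tMCAO and 3 Sham Sprague-Dawley rats 14 days after surgery, and libraries were prepared with standard Illumina protocols, per the labels' protocols. FPKM values, which scale fragments by transcript length and by mapped fragments, were computed per gene by the authors and deposited as one table with a column per library, per the file headers. The submitters' processing notes name FastQC, cutadapt, HISAT2 2.0.4 and StringTie 1.2.3. The genome build and annotation release are not given in the sources used here, so coordinates are those of the deposited table. The table held 15269 genes, all typed as protein coding, of which 69 had no name, 120 shared a name with an earlier row and 23 were listed at 0 in every library. No column belonged to a sample outside the series. The labels gave the group of each library, and replicates were numbered in accession order, so replicate numbers pair nothing. Each library came from 1 rat, as far as the labels say, and the p-values measure the spread between these rats. No batch was given.

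Depth is unknown, because FPKM keeps no counts. Low values (under 0.3 FPKM) were compared between libraries for common ratios that would give the relative worth of 1 read. The commonest ratio, in bins of 0.01 on the natural log scale, held 8 to 14 of 342 to 383 low genes in pairs without tMCAO replicate 1 and 2 or 3 of 88 to 113 in pairs with it, too few to recover reads. No interval for counting error was therefore computed. A value of 0 can be a failed estimate, so such genes are described as listed at 0.

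Genes were kept where the FPKM was at least 1 in at least 3 of the 6 libraries (13087 kept, 2182 not tested). They were tested on log2(FPKM + 1) with limma 3.58.1 (trend on) in R 4.3.3, tMCAO against Sham with no covariates, with Benjamini-Hochberg adjustment and a threshold of 0.05. Differences are on the log2(FPKM + 1) scale, which understates changes of genes with low values. A second count required a log2 difference of at least 1 on that scale, called 2-fold here, and a loose one an unadjusted p under 0.05 with that size. All tests were two-sided. Median SE of a log2 difference was 0.210, and 0.118 without tMCAO replicate 1.

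A set of 44 gene lists (cell types, hippocampal subfields, neighbouring regions and pathways) was fixed before the data were examined, as were the design, the alternatives and the naming rule. The 42 lists with at least 3 tested members were tested with camera at a preset correlation of 0.01 between genes. Lymphocytes and granulocytes, and sex-linked genes, had too few tested members. Camera with the correlation estimated per list and fry were alternatives. Members were also adjusted over the list alone.

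The naming rule took the genes of largest change that passed, and where fewer than 5 passed in a direction, the genes of smallest p whose groups did not overlap, up to 5. It added up to 4 members of smallest p of each list described, and Gfap, Aif1, Cd68, Mbp, Rbfox3, Ttr and Bdnf. Here the first 3 members of each list that passed and the first 2 of each other list are named, some only by name, except for members that are not reported here. Genes without a proper symbol were not named. The 10 genes furthest above and below Sham in tMCAO replicate 1, and single genes outside the rule, were chosen after their values were seen.

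Alternatives were a pseudocount of 0.1, no filter beyond a value above 0 in at least 1 library, a filter at a mean FPKM of at least 5, median-ratio scaling, robust limma, limma with array weights and leaving out each library in turn. Added after seeing the data were counts of genes whose groups do not overlap, counts of genes 2-fold from Sham in tMCAO replicate 1, robust limma and array weights for single genes, and camera with an estimated correlation without tMCAO replicate 1.

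The fit was tested on simulated data with 200 changed genes among 13087. In 6 libraries that varied like Sham, 91 of 100 genes changed by 1 on the log2 scale and 98 of 100 changed by 2 were recovered, with 9 false calls. When 1 library was given the observed deviation of tMCAO replicate 1, 22 and 55 of 100 were recovered, with 0 false calls. Camera recovered a list shifted by 0.5 with 0 false calls, in simulated genes that were independent of each other. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.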

Results

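Messenger RNA levels were measured by RNA sequencing in the hippocampus of 6 Sprague-Dawley rats, taken 14 days after surgery. In 3 rats the left middle cerebral artery had been closed with a filament for 90 min and then reperfused, a model of ischemic stroke called transient middle cerebral artery occlusion (tMCAO). The 3 Sham rats had the same surgery without the occlusion. The series set out to find genes related to cognitive impairment after stroke. Each rat gave 1 library, and the labels do not say which side of the brain was taken. The table held 15269 protein-coding genes as FPKM, whose sums ran from 436588 to 476319 per library. Read counts and sequencing depth were unknown. Of these genes, 13087 reached an FPKM of at least 1 in at least 3 libraries and were tested.

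Hippocampus of tMCAO rats showed no gene that changed past the threshold against Sham, and 1 of the 3 tMCAO libraries differed strongly from the other 5. In tMCAO replicate 1, microglial, complement, interferon and lysosomal genes stood far above Sham and neuronal and synaptic genes far below. In tMCAO replicate 2 the medians of the immune lists lay slightly above Sham, in replicate 3 those of both microglial lists and of antigen presentation lay within the spread of the Sham libraries, and in both replicates genes of inhibitory neurons and of cholesterol synthesis lay below Sham. With limma and Benjamini-Hochberg adjustment, 0 genes rose and 0 fell, and the smallest adjusted p was 0.718. At an unadjusted p under 0.05 there were 287 genes, where chance would give 654.35. This number was 101, 134 and 98 without Sham replicate 1, 2 or 3, and 1180 with array weights. Of the 287 genes, 17 also differed by at least 1 on the log2 scale, 10 higher and 7 lower in tMCAO. This count of 17 became 27, 83 and 57 when tMCAO replicate 1, 2 or 3 was left out, 8 without Sham replicate 2, 36 with a pseudocount of 0.1, 9 with a filter at a mean FPKM of 5 and 29 with array weights. Without tMCAO replicate 1, limma again called 0 genes (smallest adjusted p = 0.430), and 967 genes had an unadjusted p under 0.05. Without tMCAO replicate 3, 1 gene fell, an uncharacterised locus listed at 0 in tMCAO replicates 1 and 2.

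The 3 tMCAO values all lay above the 3 Sham values for 1276 genes (9.75% of those tested) and all below for 861 (6.58%), where chance gives 5% each way. With median-ratio scaling the balance turned, to 1068 above and 1107 below. The 5 genes of smallest p among those higher in tMCAO were Il15, Moxd1, Acta2, Cxcl12 and Ap1g2, none of which passed adjustment (adjusted p = 0.718 for each). Il15, a cytokine gene on chromosome 19 (23542889 to 23554594), had 2.00 ± 0.074 FPKM in tMCAO and 0.522 ± 0.114 in Sham (SD, n = 3 each), a log2 difference of 0.98 ± 0.15 (SE). Acta2, which encodes smooth muscle actin, had 13.9 ± 3.07 FPKM against 6.88 ± 1.15, and the chemokine gene Cxcl12 had 16.1 ± 3.42 against 8.39 ± 1.22. Moxd1, a monooxygenase gene, had 12.6 ± 2.77 FPKM against 6.79 ± 0.085. Ap1g2, which encodes a subunit of a vesicle coat adaptor, had 5.18 ± 1.68 against 2.20 ± 0.056.

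In the other direction the 5 genes of smallest p were Calb2, Npy, Gabrg1, Cbln4 and Pdxk, and again none passed adjustment (adjusted p = 0.718 for each). Calb2, which encodes the calcium-binding protein calretinin (chromosome 19, 41482728 to 41509658), had 3.89 ± 1.41 FPKM in tMCAO and 14.7 ± 4.0 in Sham (SD, n = 3 each), a log2 difference of -1.70 ± 0.30 (SE). Npy, which encodes neuropeptide Y (chromosome 4, 79557854 to 79565097), had 18.7 ± 0.069 FPKM against 27.6 ± 1.27. Gabrg1, a GABA receptor subunit gene, had 24.2 ± 2.89 FPKM against 34.7 ± 0.157, and Cbln4, a synaptic organiser gene, had 1.0 ± 0.465 against 3.80 ± 1.48. Pdxk, the pyridoxal kinase gene, had 12.6 ± 0.947 against 17.2 ± 1.21. Adjusted over the list alone, Npy passed in the inhibitory neuron list (adjusted p = 0.0302), and Calb2 passed in the thalamus and habenula list (adjusted p = 0.0152) and in the neurogenesis list (adjusted p = 0.0166). No other list member passed this way. This adjustment was made within each list and not over the 42 lists, so these passes carry no correction for the number of lists.

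**Figure D1:**
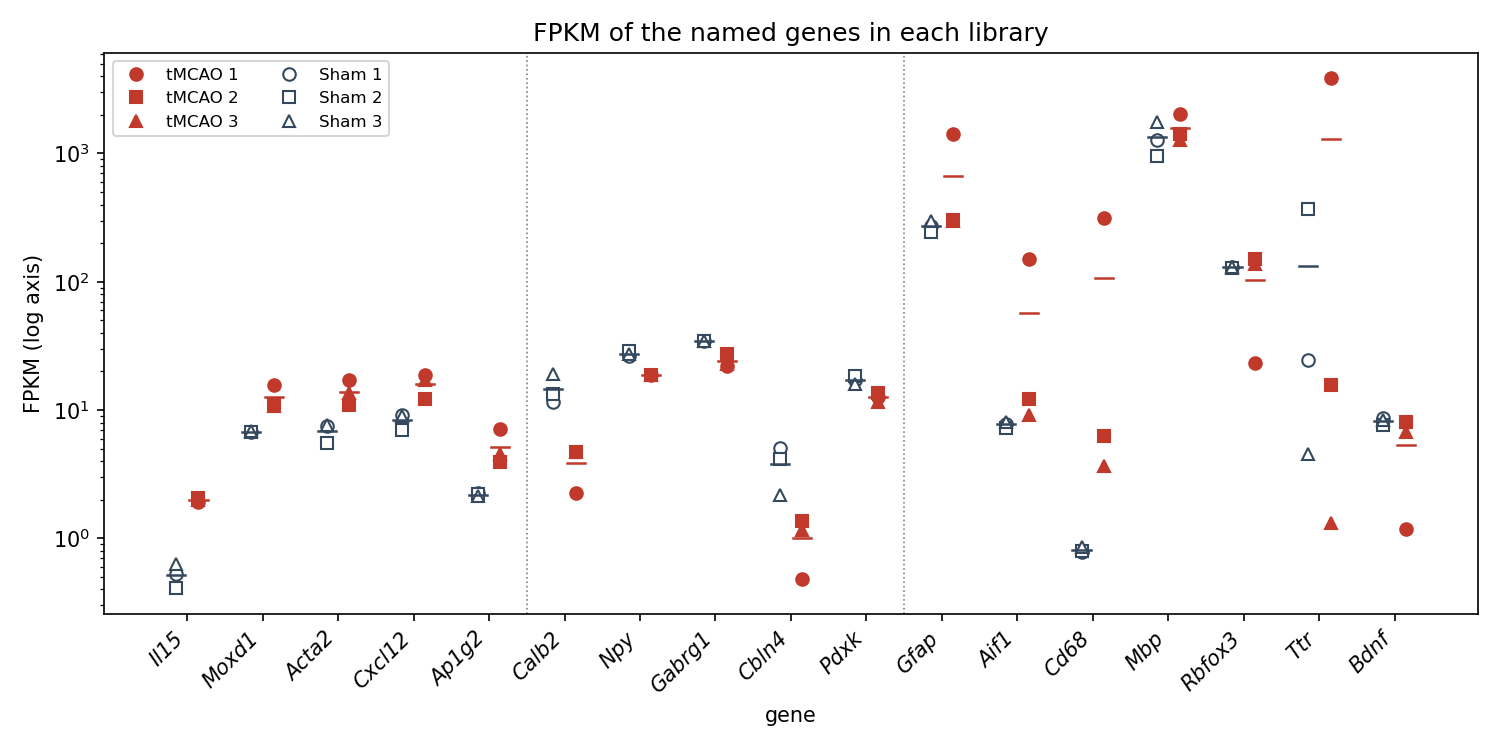
FPKM on a log axis of 17 genes in each of the 6 libraries, with open symbols for Sham, filled symbols for tMCAO, one symbol shape per replicate number, and a short line at each group's mean. The 5 genes at the left lay higher in all tMCAO libraries and the 5 in the middle lower, while for genes at the right such as Cd68 the tMCAO mean of 107 FPKM was set by replicate 1 with 312 FPKM.

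Microglial lists lay above Sham, far more in tMCAO replicate 1 than in replicates 2 and 3, with a median log2 difference between the groups of 1.70 for activated microglia and macrophages and 1.22 for homeostatic microglia (0.29 and 0.26 without tMCAO replicate 1). Of 17 genes of activated microglia and macrophages, 9 were higher in all 3 tMCAO libraries than in any Sham library, and the list's median log2 difference from Sham was 4.51 in tMCAO replicate 1, 0.36 in replicate 2 and 0.22 in replicate 3. Each Sham library set against the other Sham libraries had a median between -0.04 and 0.24. Here and below, such Sham differences were taken from a mean of fewer libraries than the tMCAO differences, which can widen the Sham spread. Cd68, a lysosomal protein of phagocytes, had 312, 6.23 and 3.67 FPKM in the 3 tMCAO libraries and 0.815 ± 0.041 in Sham (SD, n = 3). Gpnmb had 420, 12.2 and 14.3 FPKM against 5.59 ± 1.57, and Lgals3, which encodes galectin 3, had 188, 3.46 and 4.46 against 1.51 ± 0.712. Of 13 homeostatic microglial genes, 5 were higher in all tMCAO libraries, among them the transcription factor genes Sall1 and Spi1 and the microglial marker Aif1, with list medians of 3.09, 0.41 and 0.11 against -0.14 to 0.11 in Sham. As groups both lists shifted up by camera, a test of a list against the other genes (adjusted p = 2.81e-04 for activated and 3.58e-04 for homeostatic genes). With an estimated correlation between genes neither passed (adjusted p = 0.678 for both), and 0 members of either list passed the test singly.

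Immune signalling genes were likewise highest in tMCAO replicate 1. Of 18 complement genes, 8 were higher in all tMCAO libraries, with list medians of 3.94, 0.51 and 0.23 in replicates 1 to 3 and of -0.11 to 0.20 in the Sham libraries. Among them, C2 had 175, 8.38 and 4.98 FPKM against 3.00 ± 0.312 in Sham, and the complement inhibitor gene Serping1 had 176, 6.34 and 15.2 against 4.41 ± 1.39 (SD, n = 3). Cfp, the properdin gene, came between them by p, but its groups overlapped, at 14.1, 8.31 and 6.20 FPKM against 5.29 to 6.49. Of 26 interferon response genes, 10 were higher in all tMCAO libraries (medians 4.27, 0.30 and 0.16), including the transcription factor genes Irf9 and Irf1 and the ubiquitin ligase gene Dtx3l. Irf9 had 60.0, 12.9 and 17.3 FPKM against 10.7 ± 0.207. Of 21 lysosomal genes, 9 were higher in all tMCAO libraries, and the protease genes Ctss and Ctsz ranked after Cd68. That list had medians of 3.16, 0.174 and 0.093, against -0.115 to 0.090 in Sham, so that replicate 3 lay at the edge of the Sham spread. Of 18 genes of toll-like receptor and NF-kB signalling, 4 were higher in all, as were 4 of 10 cytokine and chemokine genes, led by Cxcl12, Cxcl16 and Il33. Tnfaip3, Irak4 and Casp1 had the smallest p of the toll-like receptor list, but Irak4 at 1.23 FPKM in tMCAO replicate 3 lay below the Sham libraries (1.31 to 1.48). Of 18 antigen presentation genes, 2 were higher in all, with medians of 3.61, 0.24 and -0.005 against -0.20 to 0.09 in Sham. RT1-N3, RT1-DMb and Tapbp led that list, and RT1 genes belong to a multigene family whose shared reads leave single values uncertain. All 6 lists shifted up by camera, with adjusted p of 4.91e-05 for complement, 2.56e-06 for interferon response, 5.50e-05 for lysosome, 5.94e-04 for toll-like receptor signalling, 0.0308 for cytokines and 3.33e-04 for antigen presentation. None passed with an estimated correlation (adjusted p = 0.678 for each), and no member passed singly. Leaving out tMCAO replicate 1, antigen presentation no longer passed (adjusted p = 0.376), and the other 5 passed camera but not with an estimated correlation (adjusted p = 0.629 for lysosome and 0.521 for each of the others).

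For the genes with the largest excess in tMCAO replicate 1, the other tMCAO libraries showed a small share of the same excess. Genes were taken that in replicate 1 were at least 4-fold above every Sham library and at least 20 FPKM above the Sham mean. Of these, 59 belonged to the microglial, complement and interferon lists. Over these 59, the mean of replicates 2 and 3 exceeded Sham by a median of 1.41% of the excess in replicate 1 (quartiles 0.597% and 2.17%). Over 371 other genes chosen by the same limits it was 1.42% (quartiles 0.115% and 2.52%). The medians were 1.67% and 1.98% in replicate 2 and 0.858% and 0.75% in replicate 3, for list genes and other genes. Each Sham library set against the other Sham libraries gave medians between -0.514% and 0.144%. Single genes departed from these medians in both directions. Among them, Spp1 had 955 FPKM in replicate 1, 1.83 and 1.37 in replicates 2 and 3, and 0.464 to 2.28 in Sham. A small carry-over from replicate 1 was not excluded. The counts of immune genes higher in all tMCAO libraries may therefore not rest on independent libraries.

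Vascular lists were higher in tMCAO replicate 1 by smaller amounts. Medians were 0.75, 0.20 and 0.10 in the 3 tMCAO libraries for endothelial genes (-0.05 to 0.10 in Sham), 0.88, 0.22 and 0.20 for pericytes and smooth muscle (-0.18 to 0.19 in Sham), and 0.99, -0.04 and -0.04 for blood-brain barrier junctions, so that the junction list was not above Sham in replicates 2 and 3. Of 17 endothelial genes, 7 were higher in all tMCAO libraries, as were 5 of 12 genes of pericytes and smooth muscle and 4 of 15 genes of blood-brain barrier junctions. Vwf, the von Willebrand factor gene, had 8.33, 5.75 and 5.73 FPKM against 4.49 ± 0.215 in Sham (SD, n = 3). The transporter gene Abcb1a had 9.39, 7.46 and 7.11 against 6.01 ± 0.270, and the endothelial transcription factor gene Sox17 had 3.50, 2.05 and 2.87 against 1.69 ± 0.360. After Acta2, the potassium channel gene Kcnj8 and the smooth muscle myosin gene Myh11 led the pericyte list. Ocln, a tight junction gene, had 12.2, 4.21 and 4.22 FPKM against 2.51 ± 0.799, and Abcb1a and Cldn5 came next in that list. By camera the adjusted p was 2.24e-04 for endothelial genes, 9.09e-05 for pericytes and smooth muscle and 0.00818 for junctions, and 0.678 for each with an estimated correlation. Of these 3, only pericytes and smooth muscle passed without tMCAO replicate 1 (adjusted p = 0.00490, and 0.546 with an estimated correlation). Endothelial genes then had an adjusted p of 0.0759 and junctions of 0.955, with a junction median of -0.012.

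Glial and matrix lists were high mainly in tMCAO replicate 1. The 22 genes of reactive astrocytes had list medians of 2.77, 0.07 and 0.15 in the tMCAO libraries, with 7 genes higher in all, Tm4sf1, S1pr3 and Ggta1 having the smallest p. Medians of the 12 genes of oligodendrocyte precursors (Sox10, Cspg4 and Vcan first by p) were 0.83, 0.19 and -0.03, and 0 were higher in all. For meninges and extracellular matrix, 18 genes led by the collagen genes Col4a2, Col4a1 and Col6a1, the medians were 2.95, -0.34 and -0.20, and the Sham libraries ran from -1.16 to 0.75. Camera gave adjusted p of 3.82e-04, 0.0308 and 0.0268 for these lists, which became 0.678, 0.678 and 0.704 with an estimated correlation. Leaving out tMCAO replicate 1, none of the 3 passed, and the matrix list turned down (adjusted p = 0.0798). The matrix list also did not pass without Sham replicate 3 (adjusted p = 0.368), nor the precursor list without Sham replicate 1 or 2 (adjusted p = 0.0525 and 0.107).

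**Figure D2:**
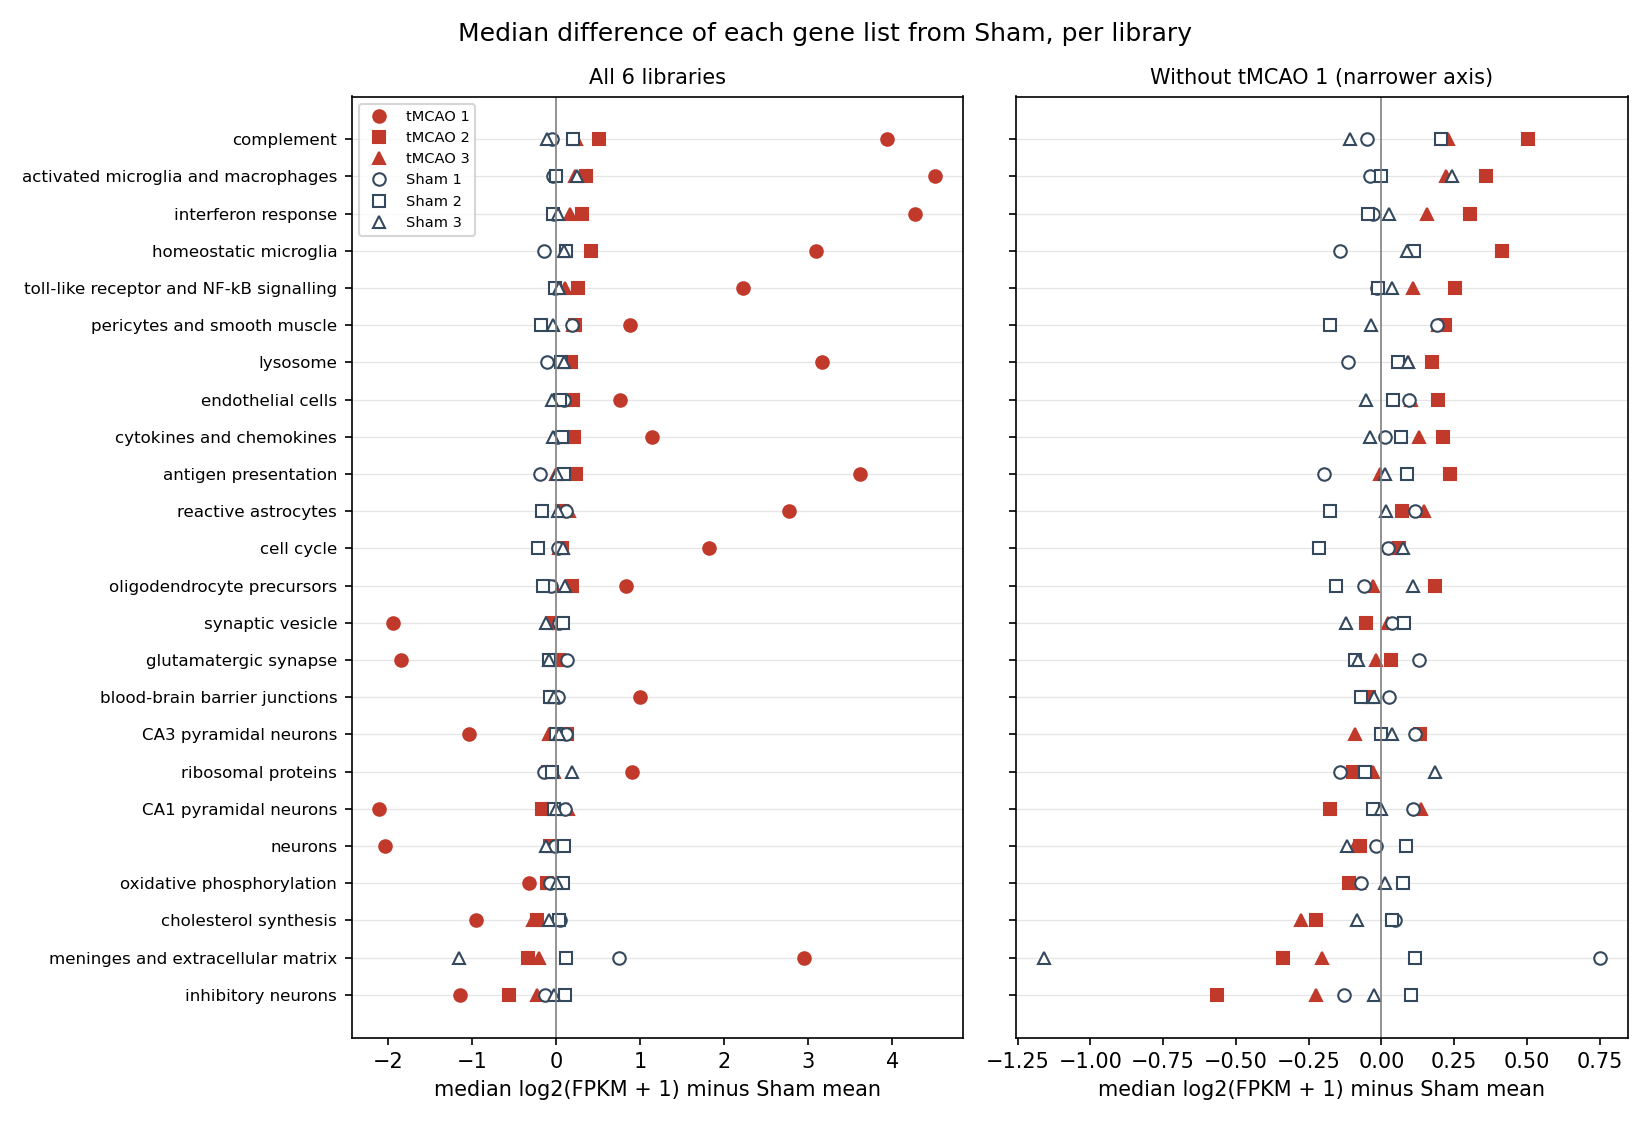
Median difference in log2(FPKM + 1) from the Sham mean for the 24 gene lists that passed camera, one point per library, with each Sham library set against the other Sham libraries; the right panel leaves out tMCAO replicate 1 and has a narrower axis. In tMCAO replicate 1 the activated microglia list lay at 4.51 and neurons at -2.04, while in tMCAO replicates 2 and 3 the inhibitory neuron list lay at -0.57 and -0.23.

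The median of the inhibitory neuron genes was below Sham in each tMCAO library. Of 19 such genes, 9 were lower in all 3 tMCAO libraries than in any Sham library, and the list medians were -1.15, -0.57 and -0.23, against -0.13 to 0.10 in the Sham libraries. After Npy came Sst, the somatostatin gene, with 73.0, 90.7 and 131.57 FPKM against 165 ± 30.9 in Sham (SD, n = 3) and groups that overlapped at Sham replicate 1 (131.549), and Dlx1, a transcription factor gene of interneurons, with 3.75, 5.86 and 8.83 against 10.8 ± 1.66. The list shifted down by camera (adjusted p = 1.92e-09) and did so without tMCAO replicate 1 (adjusted p = 3.80e-08). It did not pass with an estimated correlation (adjusted p = 0.678, and 0.521 without tMCAO replicate 1).

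Other neuronal lists were low in tMCAO replicate 1 and close to Sham in replicates 2 and 3. The 16 pan-neuronal genes had medians of -2.04, -0.07 and -0.09, with 3 lower in all. Stmn2, a microtubule regulator gene, had 64.9, 237 and 230 FPKM against 263 ± 1.01 (SD, n = 3), and Uchl1, whose groups overlapped, and Tubb3 came next by p. For 27 genes of the glutamatergic synapse the medians were -1.85, 0.03 and -0.02, and the glutamate receptor genes Grm5 and Gria4 and the scaffold gene Homer1 had the smallest p. For 18 synaptic vesicle genes (Sv2c, Syn2 and Sv2a first) they were -1.94, -0.05 and 0.02. CA1 pyramidal neuron genes, 8 in number and with Nov and Fibcd1 among those of smallest p, had medians of -2.10, -0.18 and 0.14. Fibcd1 was listed at 0 in tMCAO replicate 1. The 9 CA3 genes (Spock1, Bok and Cdh24 first) had medians of -1.04, 0.13 and -0.09. Camera gave adjusted p of 4.27e-05 for neurons, 1.72e-06 for the glutamatergic synapse, 9.26e-05 for synaptic vesicles, 0.0332 for CA1 and 0.0397 for CA3, all downward, and 0.678 for each with an estimated correlation. None of the 5 passed without tMCAO replicate 1, when the glutamatergic synapse list turned up (adjusted p = 0.845) and the synaptic vesicle median was 0.015. CA1 and CA3 were also lost without Sham replicate 1 (adjusted p = 0.0808 and 0.0782), and CA3 without Sham replicate 2 (adjusted p = 0.0520). With median-ratio scaling neither passed (adjusted p = 0.0591 for CA1 and 0.0689 for CA3), nor did CA1 with no filter (adjusted p = 0.0902).

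The medians of the cholesterol synthesis and oxidative phosphorylation lists lay below Sham in each tMCAO library. Of 21 genes of cholesterol synthesis, 14 were lower in all tMCAO libraries, with list medians of -0.95, -0.22 and -0.28, against -0.084 to 0.046 in Sham. Fdft1, the squalene synthase gene, had 15.0, 27.0 and 25.7 FPKM against 37.4 ± 1.42 in Sham (SD, n = 3), Cyp51 had 39.9, 65.9 and 51.9 against 78.4 ± 4.94, and Sqle, the squalene epoxidase gene, had 16.8, 29.3 and 23.9 against 35.6 ± 2.54. Of 24 nuclear genes of oxidative phosphorylation, 11 were lower in all, with medians of -0.329, -0.112 and -0.078. The Sham libraries ran from -0.070 to 0.074, so that tMCAO replicate 3 lay at the edge of the Sham spread. Ndufs1, Cycs and Sdha had the smallest p of the list (the groups overlapped for Sdha). Both lists shifted down by camera with all libraries (adjusted p = 3.58e-10 and 8.00e-07) and without tMCAO replicate 1 (adjusted p = 1.02e-11 and 2.32e-06). Neither passed with an estimated correlation (adjusted p = 0.678 for both, and 0.521 for both without tMCAO replicate 1). The 29 ribosomal protein genes (Rps6, Rplp0 and Rps18 first) shifted up (adjusted p = 0.00860, and 0.704 with an estimated correlation), with 0 higher in all. They turned down without tMCAO replicate 1 (adjusted p = 0.00490), a call also lost with an estimated correlation (adjusted p = 0.758). The 7 cell cycle genes (Tyms, Tpx2 and Mcm2 first) shifted up (adjusted p = 0.0221, and 0.678 with an estimated correlation), with medians of 1.82, 0.06 and 0.03. Neither the ribosomal nor the cell cycle list passed without Sham replicate 2 (adjusted p = 0.0603 and 0.0631), and cell cycle did not pass without tMCAO replicate 1 (adjusted p = 0.845).

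In total 24 of the 42 lists tested passed camera, 16 up and 8 down. Without tMCAO replicate 1, 16 passed, and 11 lists passed both ways in the same direction. With an estimated correlation 0 passed, and 0 passed by fry (smallest adjusted p = 0.622). Camera with the preset correlation also called between 21 and 30 lists in other splits of the 6 libraries into 3 and 3, so that its calls did not single out the split into tMCAO and Sham.

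Of the markers fixed in advance, none passed the test. Gfap, an astrocyte filament gene, had 1421 FPKM in tMCAO replicate 1, 301 and 296 in replicates 2 and 3, and 271 ± 27.5 in Sham (SD, n = 3). Rbfox3, which encodes the neuronal marker NeuN, had 23.2, 150 and 138 against 129 ± 0.542, and the growth factor gene Bdnf had 1.19, 8.12 and 6.73 against 8.26 ± 0.525. Aif1 had 150, 12.3 and 9.10 against 7.73 ± 0.416. Mbp, a myelin gene, had 2047, 1422 and 1271 against 1336 ± 410. Ttr, the choroid plexus gene for transthyretin, spread from 1.31 to 3839 FPKM in tMCAO and from 4.56 to 367 in Sham. Their adjusted p ran from 0.718 to 0.937, with Cd68 included.

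The distance of tMCAO replicate 1 from the rest was measured without a test, since it is a single library. Its correlation with the other 5 libraries over genes on the log2 scale was 0.765 to 0.783, whereas those 5 correlated with each other at 0.983 to 0.988. In it, 3619 genes differed from the Sham mean by at least 1 on the log2(FPKM + 1) scale, 1957 higher and 1662 lower. With a pseudocount of 0.1 there were 4279. The balance turned with median-ratio scaling (1649 higher and 1920 lower) and with a filter at a mean FPKM of 5 (1355 higher and 1460 lower). With the main settings the counts were 49 in tMCAO replicate 2 and 84 in replicate 3, and 98 to 108 for each Sham library against the other Sham libraries. The Sham counts were taken from a mean of fewer libraries, which by itself raises them, so the counts are not directly comparable. Mitochondrial genes took 8.93% of its FPKM against 13.03% to 14.4% in the others. Of the named genes furthest above Sham in this library, a rule chosen after the values were seen gave Spp1, Cd68, Cd74, Mx1, Ttr, C3, Lgals3, RT1-Da, Gpnmb and Irf7, with log2 differences from 8.66 to 5.94. Those furthest below were C1ql2, Cabp7, Lyzl4, Nts, Lrrc10b, Hpca, Hapln4, Neurod6, Shisa6 and Epha6, from -5.48 to -3.90. C1ql2, a gene of dentate granule neurons, had 0.548 FPKM in this library, 76.2 and 60.3 in tMCAO replicates 2 and 3, and 63.7 to 70.6 in Sham.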

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

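Robust limma, array weights, a pseudocount of 0.1, no filter, a filter at a mean FPKM of 5 and median-ratio scaling all left 0 genes past adjustment, with or without the 2-fold limit, as in the main result; leaving out each library in turn gave 0 to 1 gene for both counts, the 1 gene appearing without tMCAO replicate 3. Genes at an unadjusted p under 0.05 and 2-fold numbered 17, and became 36 with a pseudocount of 0.1, 9 with the stricter filter (which tests fewer genes), 29 with array weights and 8 to 83 on leaving out a library (lowest without Sham replicate 2, highest without tMCAO replicate 2). The 24 lists became 0 with an estimated correlation, 0 by fry and 0 with an estimated correlation and tMCAO replicate 1 left out, and stayed between 16 and 28 otherwise. Genes whose groups do not overlap, counted after seeing the data, numbered 3171 to 3711 on leaving out a library, since fewer samples overlap less. Median-ratio scaling moved tMCAO replicate 1 by 0.12 on the log2 scale, and changed the split of those genes from 1276 above and 861 below to 1068 and 1107, and of the genes at an unadjusted p under 0.05 from 201 and 86 to 175 and 118. Of 116 named genes, none passed adjustment in any setting, and depth could not be weighed as a limit.

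The cause of turned directions was not tested. Where a list's direction by camera turned, its median was -0.0055 (no filter) and -0.054 (scaling) for the circadian clock, -0.0037 for glucocorticoid response (stricter filter) and -0.047 for striatum (scaling). For lists that camera turned on leaving out a library, medians over those fits ran from -0.12 to 0.88 for border macrophages, -0.041 to 0.45 for myelin, -0.45 to 0.038 for dentate granule neurons, -0.92 to 0.014 for the glutamatergic synapse, -0.28 to 1.37 for meninges and matrix, -0.33 to 1.63 for choroid plexus, -0.37 to 0.48 for ependymal cells, -0.020 to 0.32 for neocortex, -0.15 to 0.089 for striatum, -0.74 to 0.58 for erythrocytes, -0.17 to 0.10 for neurogenesis, -0.070 to 0.18 for heat shock, -0.24 to 0.063 for mitochondrial-encoded genes, -0.050 to 0.43 for ribosomal proteins, -0.10 to 0.13 for the clock and -0.21 to 0.23 for glucocorticoid response. Without tMCAO replicate 1 camera turned 10 lists, and 10 further lists lost their call. Medians changed sign there for 16 lists, those 10 and blood-brain barrier junctions (-0.012), synaptic vesicle (0.015), immediate early genes (0.031), neurotrophin (-0.020), neurogenesis (0.095) and the clock (0.13).

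Genes that turned with array weights, added after seeing the data, were Rbfox3 (0.13), Ttr (-2.07), Pf4 (-0.026), Tekt1 (-0.062), Mt-nd6 (0.052), Mt-nd3 (0.018), Rps6 (-0.011), Rplp0 (-0.015) and Rps18 (-0.026). On leaving out a library, log2 differences ran from -1.17 to 0.15 for Rbfox3, -2.59 to 2.76 for Ttr, -0.048 to 1.77 for Pf4, -0.078 to 0.90 for Tekt1, -0.36 to 0.022 for Ccdc153, -0.24 to 0.0011 for Bpgm, -0.42 to 0.055 for Mt-nd6, -0.35 to 0.030 for Mt-nd3, -0.011 to 0.73 for Rps6, -0.025 to 0.77 for Rplp0 and -0.0091 to 0.56 for Rps18.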

Other observations

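The tests of explanations and of other splits in this part were chosen after the results were seen, unlike the list tests. With all 6 libraries 18 lists did not pass camera. The 8 choroid plexus genes (Cox8b and Calml4 first by p) had list medians of 3.51, -0.24 and -0.52 in the tMCAO libraries, with adjusted p = 0.109. Ependymal genes (Tekt1 and Ccdc153 first) had 1.15, -0.22 and -0.60 (adjusted p = 0.931), blood and border macrophages (Ly86 and Pf4) 1.73, -0.23 and -0.13 (adjusted p = 0.222), and erythrocytes (Bpgm among the first by p) 1.80, -0.13 and -1.09 (adjusted p = 0.496). Myelin genes (Gjb1 and Hapln2) had 0.68, -0.01 and -0.10 (adjusted p = 0.0755), and Sham replicate 2 lay at -0.76 and Sham replicate 3 at 0.65 against the other Sham libraries. Astrocyte genes had 0.33, 0.02 and 0.06 (adjusted p = 0.337), Sox9 and Atp1b2 being first. Among regions, the thalamus and habenula list, where Ramp3 followed Calb2, had -0.46, 0.06 and -0.02 (adjusted p = 0.121), neocortex (Mef2c and Ctgf) -0.06, 0.03 and 0.33 (adjusted p = 0.376), and striatum (Ppp1r1b and Adora2a) 0.22, -0.05 and -0.01 (adjusted p = 0.931). Zic1, chosen after its values were seen, was at 29.3 FPKM in Sham replicate 3 and between 3.42 and 13.9 in the other libraries.

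Dentate granule genes (Calb1 and Stxbp6) had medians of -0.79, 0.16 and -0.09 (adjusted p = 0.333), and neurogenesis genes, where Cd24 followed Calb2, had -0.004, -0.06 and 0.20 (adjusted p = 0.652). Immediate early genes (Dusp6 and Fosb) had -0.31, -0.11 and 0.03 (adjusted p = 0.337). Monoamine and peptide transmission (Chrna7 and Htr2a) had -0.93, -0.03 and -0.01 (adjusted p = 0.1204), and neurotrophin and growth factor genes (Vgf and Pdgfb) 0.33, 0.07 and 0.02 (adjusted p = 0.931). Heat shock and hypoxia genes (Hsp90aa1 and Ddit3) had 0.10, -0.07 and -0.11 (adjusted p = 0.931), mitochondrial-encoded genes (Mt-nd6 and Mt-nd3) -0.52, 0.03 and 0.07 (adjusted p = 0.117), circadian clock genes (Bhlhe41 and Per3) -0.12, 0.02 and 0.18 (adjusted p = 0.931), and glucocorticoid response genes (Mt2A and Mt1) 0.58, -0.15 and -0.34 (adjusted p = 0.931). For the clock list the median log2 difference was -0.0055 while camera and the mean (0.015) pointed up, and for the glucocorticoid list the median was -0.0037 and camera pointed down while the mean was 0.16.

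Several of these lists passed camera in another setting. Without tMCAO replicate 1, ependymal genes (adjusted p = 0.00170), erythrocytes (0.0458) and glucocorticoid response (0.0248) passed downward and the circadian clock upward (0.0458). None of these did with an estimated correlation (adjusted p = 0.546, 0.521, 0.529 and 0.688). The medians of tMCAO replicates 2 and 3 both lay within the Sham range for erythrocytes (-1.17 to 1.44) and glucocorticoid response (-0.352 to 0.187). That of replicate 2 also did for ependymal genes (-0.357 to 0.52) and the clock (-0.116 to 0.077). Myelin genes passed upward without Sham replicate 3 (adjusted p = 4.14e-06), without tMCAO replicate 3 (0.0128) and with a filter at a mean FPKM of 5 (0.0378), and turned down without Sham replicate 2 (0.424). Choroid plexus passed upward with no filter (adjusted p = 0.0102) and without tMCAO replicate 3 (0.00743). Monoamine and peptide transmission passed downward with no filter, with the stricter filter and without tMCAO replicate 3 (adjusted p = 0.0406, 0.0347 and 0.0346), thalamus and habenula with the stricter filter (0.0399), and mitochondrial-encoded genes without tMCAO replicate 3 (0.0434). An estimated correlation was not tried in the settings that kept tMCAO replicate 1, except with all libraries, where no list passed.

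One pattern was the distance of tMCAO replicate 1 from the other 5 libraries. A loss of neurons alone would raise all other cell types alike, but activated microglia genes lay above astrocyte genes by a median of 4.18 on the log2 scale, with quartiles that did not meet (2.73 to 5.34 and -0.40 to 0.69). Intact grey matter of a neighbouring forebrain region would keep pan-neuronal genes near Sham, and their median was -2.04. Damaged grey matter of such a region could also lose neuronal genes, so this comparison cannot judge it. Choroid plexus in the dissection could raise the choroid genes, whose median was 3.51. Homeostatic microglia genes had a median of 3.09, but macrophages of choroid plexus may share genes of that list, such as Spi1 and Aif1. The comparison therefore cannot exclude choroid plexus as a contributor. White matter in the sample would raise myelin genes, whose median was 0.68 (quartiles 0.48 to 0.98), while Sham replicate 3 lay at 0.65 against the other Sham libraries. Those quartiles lay below the ones of activated microglia genes, which argues against white matter alone as the source of the higher microglial genes. An infarct or other injury that reached the tissue of this rat was not tested and stays open. The same holds for a sample of damaged tissue, white matter or a neighbouring region included, and for a label from outside the series.

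Another pattern was the shift of microglial, complement and interferon genes above Sham in tMCAO replicates 2 and 3 as a pair, although both microglial medians in replicate 3 (0.107 and 0.223) lay within the spread of the Sham libraries (up to 0.113 and 0.243). More meninges, choroid plexus or border macrophages would raise those lists, whose joint median without tMCAO replicate 1 was -0.26 against 0.29 for the immune lists. RNA or reads carried over from tMCAO replicate 1 would add one common share of its excess to every gene. The medians were alike for list genes (1.41%) and for genes outside them (1.42%). Of 39 genes with an SE under 0.3, 13 lay more than 3 SE under 1.41% and 5 more than 3 SE above. Of the 13, 3 lay more than 3 SE under 50% of that share. This SE came from the spread of the Sham libraries alone, and the genes were chosen for a small one. These departures therefore cannot decide whether single genes differed from a common share. Of 215 genes with at least 50 FPKM above Sham in replicate 1, 4 (Spp1, Ttr, Kcnj13 and Mx1, chosen after their values were seen) had whole levels in replicates 2 and 3 under 50% of what the list medians of 1.67% and 0.858% would add, and Spp1 stood at 0.192% and 0.143% of its level in replicate 1. The levels of these 4 genes argue against one common share as the whole source. A smaller carry-over, and a milder form of the same tissue response, which was not tested, stay open.

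The last pattern was the lower inhibitory neuron genes in tMCAO. Fewer neurons of every kind in tMCAO replicates 2 and 3 would lower pan-neuronal genes by as much, but their median was -0.0855 (quartiles -0.12 to 0.04) against -0.39 (quartiles -0.53 to -0.21) for inhibitory neuron genes. Neighbouring tissue in Sham replicate 3 would make the difference shrink without that library. The list median was then -0.62, against -0.55 with all 6 libraries, so Sham replicate 3 did not enlarge it. No fit left out tMCAO replicate 1 and Sham replicate 3 together, so the difference in tMCAO replicates 2 and 3 alone was not judged. Camera at the preset correlation gave an adjusted p of 1.59e-10 without Sham replicate 3. An estimated correlation was not tried there, and with all libraries the list did not pass with it (adjusted p = 0.678). A change in these neurons or in their transcripts after the occlusion, and differences in dissection along the hippocampus, remain as untested hypotheses.

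With 3 against 3 there are 10 splits of the libraries, too few for a share under 0.05. The real split gave 24 lists and the highest other split 30, with 5 of 10 splits giving as many. For genes at an unadjusted p under 0.05 and 2-fold, the real count was 17 and the highest other 27, with 6 of 10 giving as many. The count of 0 adjusted calls, with or without the 2-fold limit, was given by 10 of 10. Genes whose groups did not overlap numbered 2137, with 1531 the highest other (1 of 10), and genes at an unadjusted p under 0.05 numbered 287, with 255 the highest other (1 of 10). Without tMCAO replicate 1, which leaves 10 splits into 2 and 3, 16 lists compared with 18 in the highest other split (3 of 10 as many), and 967 genes at an unadjusted p under 0.05 compared with 980 (2 of 10 as many).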
